A study of Homo sapiens with 8 samples.

How the data were processed

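Gene expression was measured on 8 Affymetrix human arrays with 54675 probe sets, 2 arrays in each of the 4 groups 30U, 30D, 180U and 180D. Per the labels, cells were taken through 4 rounds of transwell selection, grown for 2 passages after harvest, and each D subline shares its parental population with 1 U subline. The deposited values are log2 expression values made by the authors with RMA, which corrects background, normalizes between arrays and summarises the probes of a probe set, per the submitters' processing notes. The RMA version is not given in the sources used here. Values in the table ran from 1.44 to 14.01. RMA makes the distributions of the arrays alike, so a change in the total amount of RNA per cell would not be seen, and it compresses low signals, so fold changes of dim genes are understated. MicroRNA arrays of the same RNA, which the labels mention, were not used here.

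Probe sets were named through the platform annotation. Of them 41091 had 1 gene symbol, 1801 had several, 11721 had none listed and 62 were controls. Symbols were updated by Entrez ID through a RefSeq gene table of assembly GRCh38.p14, which matched 41037 of the probe sets with 1 symbol and served only for names and for which genes neighbour each other. Only probe sets with 1 symbol were tested. Those with a mean over the 8 arrays under the 40th percentile of all probe sets, a log2 value of 4.46, were left out, and each gene was represented by its probe set with the highest mean. This left 14180 of 19775 genes, 7012 of them with more than 1 probe set past the filter. Where 1 of the groups compared had a mean below the filter value, a change within a line was also measured from that value and given as a lower bound. This was chosen after the data were seen, and the filter value stands in for background, since it is not a detection call. Other probe sets of a named gene moved the other way past the threshold for 1 gene, TAP2, in the comparison of the lines (-0.86, against 1.14 for the probe set used).

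Tests used limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A fit of the 4 group means gave the change from U to D within each line and the difference between these changes. An additive fit with cell line and fraction gave the change over both lines and the difference between the lines. Groups of 2 arrays share 1 estimate of the spread in these fits, the number of arrays limits the precision, and the p-values measure the spread between separately selected populations. The 23 gene lists and 5 lists of cell type markers, holding 848 symbols of which 669 were tested, were tested with camera at its preset correlation of 0.01, adjusted over the 28 lists in each comparison. They cover epithelial junctions, the mesenchymal state, squamous differentiation, basal squamous cells, integrins and focal adhesion, matrix proteases and inhibitors, actin motility machinery, the cell cycle, the type I interferon response, inflammatory cytokines and NF-kB targets, the TGF-beta response, EGFR ligands and receptors, AP-1 and immediate early genes, NRF2 targets, hypoxia and glycolysis, cholesterol synthesis, the unfolded protein and ATF4 response, p53 targets, Wnt and Notch readouts, let-7 and oncofetal genes, cancer-testis antigens, MHC class I and II, and cytosolic ribosomal proteins. The marker lists cover fibroblasts, immune cells, endothelial cells, neural or melanocytic cells, and simple or glandular epithelium. Camera compares a list with the other genes, whereas fry tests whether the genes of a list move on balance one way and does not compare them with other genes. Camera was also run with the correlation estimated from the data. A higher p in that run does not by itself show that the genes of a list vary together. For the difference between the lines the estimate was 0.107 for MHC genes but -0.00427 for p53 targets, under the preset. The camera p of both rose with it, from 3.07e-07 to 0.0273 and from 0.000693 to 0.0208.

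Groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. In each comparison the rule names up to 10 genes higher and 10 lower with the largest change among those past the threshold, the 5 with the smallest p in a direction where fewer than 3 passed, up to 4 members with the smallest p of each list described, and always CDH1, CDH2, VIM, FN1, ZEB1, SNAI2, MMP1, ITGA6, KRT5, KRT14 and TP63. ZEB1 lay below the filter, with a mean of 3.30, and TP63 had no probe set with 1 symbol, so neither was tested. Where at most 5 members of a list moved one way, members outside the rule are named after their values were seen, and not all of these were refitted without each array. Provisional LOC symbols, XIST and Y-linked genes were not named. A list of 24 targets of YAP and TEAD, 22 of them measured, was added after the others for 1 test in the closing observations.

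Alternatives were other filters on dim probe sets, the mean of all probe sets or every probe set on its own, quantile normalization once more, centring of each array, an intensity trend or robust eBayes, fits on the arrays of 1 line, other averages of the contrasts, a 2-fold threshold, and leaving out each array in turn. In a fit that leaves a group with 1 array, that array is taken to vary like the other groups. The parental population and the number in the titles were also used as a block, and the parental population as a random block with statmod 1.5.0. The parental population pairs the arrays by the labels. Deviations of the paired arrays from their group means correlated at -0.0228 across genes in KYSE30 and at 0.0203 in KYSE180, where the title numbers cross the pairs. With 2 arrays in a group the deviations mirror each other. Crossing the pairs therefore only turns the sign, to -0.0203, and is not a second measurement.

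The steps were tested on simulated data with the real means and spreads of 14180 genes, 100 of them changed by each log2 size. At a change of 0.5 the share recovered was 89% for 30D against 30U, 84% for 180D against 180U, 48% for the difference between the lines, 97% over both lines and 92% between the lines. At a change of 1 these shares were 98%, 100%, 96%, 100% and 100%, and between 4.17% and 6.64% of all calls were false. The residual spread of the additive fit holds any difference between the changes of the lines. Its shares, over both lines and between the lines, therefore do not cover genes whose change from U to D differs between the lines. In the real data 1723 genes passed the test of that difference, and recovery over both lines at a given size would be lower for them. A shifted list was found (adjusted p = 4.13e-70) with 0 of 27 other lists past the threshold. The simulated noise was independent between genes, so this does not test camera on lists whose genes vary together. For runs of neighbouring genes, windows of 51 genes moved in steps of 5 along 14139 genes, and a planted run of 60 genes was found, with 0 of 200 shuffles as extreme against 92 of 200 with no run. Figures were drawn with matplotlib 3.10.9.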

Results

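Transcript levels were measured on 8 Affymetrix arrays in sublines of KYSE30 and KYSE180, established human esophageal squamous cell carcinoma lines. Each line had been put through 4 successive rounds of transwell selection, in which cells move through a porous membrane. Cells that passed through it form the D sublines, which the labels describe as the more motile ones, and cells that did not pass form the U sublines. The 4 groups, called 30U, 30D, 180U and 180D, held 2 arrays each. Each D subline and its U partner came from 1 of 4 independent parental populations, so the spread within a group is that between separately selected populations. The comparisons ask which transcripts differ between the more and the less motile cells of each line, and whether both lines changed alike. All changes are log2 differences, D minus U unless stated, given with their SE from 2 arrays per group, and this small number of arrays limits their precision.

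Arrays of the same group correlated most closely, with r between 0.997 and 0.998 across the tested genes in 4 pairs of arrays. U and D arrays of the same line correlated at 0.992 to 0.995, and arrays of different lines at 0.860 to 0.869. The first principal component, which parted the lines, held 94.4% of the variance, and the next held 2.44%. Array medians over all probe sets lay between 5.02 and 5.04 on the log2 scale. The array of 180D replicate 1 stood apart in its control probe sets. The signal of the 3′ end of ACTB, the beta-actin gene, exceeded that of the 5′ end by 1.92 there, against 1.06 to 1.42 on the other 7 arrays, and its 18S ribosomal RNA control read 11.47 against 12.35 to 12.54.

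In KYSE30, GJA1, which encodes the gap junction protein connexin 43, had the largest fitted change (-4.73 ± 0.06, limma adjusted p = 7.86e-08), with mean log2 levels of 7.62 in 30U and 2.89 in 30D. The 30D level lay below the filter value of 4.46, and measured from that value GJA1 was at least 8.94-fold lower. KLHL13, a substrate adaptor of cullin-3 ubiquitin ligases, IGFBP5, FREM2, CNTN1 and PALMD also lay below it in 30D and were at least 3.65-fold, 1.79-fold, 2.53-fold, 3.62-fold and 3.24-fold lower, while C1orf21 fell 6.15-fold. IGFBP5 is a secreted binding protein for insulin-like growth factors and FREM2 an extracellular matrix protein. CNTN1 is a cell adhesion molecule of the immunoglobulin superfamily. EPB41L4A changed by -2.20 ± 0.09. SOX2, a transcription factor amplified in many squamous carcinomas, fell from 9.80 to 7.86 (-1.94 ± 0.05), and BCAT1, the cytosolic branched-chain aminotransferase, from 10.13 to 8.21. Among the genes higher in 30D, RFTN1, a lipid raft protein, led with 5.19-fold (2.37 ± 0.09, adjusted p = 3.38e-05). It was followed by the interferon-inducible genes IFI6 (1.96 ± 0.10), GBP1 (1.94 ± 0.10) and IFI27, which lay below the filter value in 30U and was at least 2.36-fold higher. COXFA4L3, LAMP3 and IFI44 rose 3.07-fold, 2.92-fold and 2.58-fold. IL1RN, the interleukin-1 receptor antagonist, rose by 1.44 ± 0.07, the chemokine CCL5 by 1.33 ± 0.08 and PRR15L by 1.31 ± 0.17.

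Of 14180 genes tested, 2346 differed between 30D and 30U, 1194 of them higher and 1152 lower in 30D. With each array centred on its median the balance turned, to 1066 higher and 1311 lower. At least a 2-fold change was reached by 85 genes, 29 higher and 56 lower. The count depended on the arrays of KYSE30 itself and was 902 without 30U replicate 1, 834 without 30U replicate 2, 902 without 30D replicate 1 and 873 without 30D replicate 2. All of the 20 genes named above kept their call in each of the 8 fits that left out 1 array.

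The type I interferon response list moved furthest in 30D. Of its 37 measured members 28 rose, 1 fell and 8 did not pass the test, while 29 rose and 2 fell when adjusted over the list alone. Besides IFI27, IFI6 and GBP1, ISG15, a ubiquitin-like modifier, rose by 1.15 ± 0.05. The member that fell was IFIT2 (-0.49 ± 0.06). The list's median change was 0.71 (camera adjusted p = 1.72e-20, and adjusted p = 0.0102 with an estimated correlation). The MHC class I and II list, which shares PSMB8 and PSMB9 with the interferon list, also rose. Of its members 10 of 16 were higher and none lower (adjusted over the list alone, 12 higher). Examples were TAP1 (0.81 ± 0.06) and PSMB9 (0.68 ± 0.07), a peptide transporter subunit and an immunoproteasome subunit, and HLA-F (0.56 ± 0.06). The median was 0.41 (camera adjusted p = 3.26e-07, and adjusted p = 0.151 with an estimated correlation).

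Cholesterol synthesis genes fell in 30D. Of 22 measured members 14 fell, PMVK rose (0.25 ± 0.07) and 7 did not pass, with 14 lower and 1 higher when adjusted over the list alone. INSIG1, a sterol-responsive regulator of the pathway, changed by -1.07 ± 0.06, HMGCS1, the HMG-CoA synthase, by -0.62 ± 0.05, STARD4, a sterol carrier, by -0.54 ± 0.06 and the isomerase IDI1 by -0.53 ± 0.06. The list's median was -0.26 (camera adjusted p = 5.01e-08, and adjusted p = 0.0406 with an estimated correlation). The rise of PMVK was not kept with the parental population as a block (adjusted p = 0.103).

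**Figure D1:**
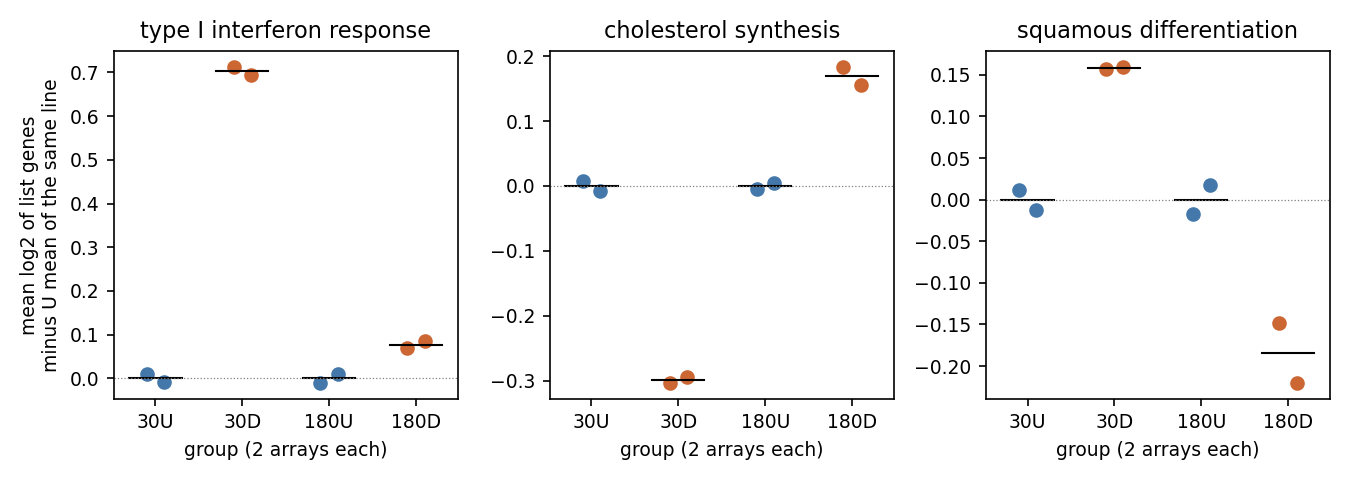
Mean log2 level of the measured genes of 3 lists on each of the 8 arrays (points), relative to the mean of the U arrays of the same line, with group means as bars. The interferon list has a median change of 0.71 in KYSE30 and 0.14 in KYSE180, the cholesterol list -0.26 and 0.16, and the squamous differentiation list 0.19 and -0.13.

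Lists of growth control shifted downwards in 30D. In the cell cycle list 17 of 50 genes fell, AURKA rose (0.23 ± 0.05) and 32 did not pass, with 19 lower and 1 higher when adjusted over the list alone. The replication genes MCM7 and TYMS changed by -0.49 ± 0.06 and -0.46 ± 0.05, and the median was -0.13 (camera adjusted p = 8.56e-05, but adjusted p = 0.344 with an estimated correlation). Among p53 targets 8 of 20 fell and TP53I3 rose (0.54 ± 0.06), with 9 lower and 1 higher when adjusted over the list alone. GDF15, a stress-induced cytokine of the TGF-beta superfamily, fell by 1.52, TP53INP1 by 0.96, the cyclin-dependent kinase inhibitor CDKN1A by 0.95 and SESN1 by 0.72 on the log2 scale (camera adjusted p = 0.000385, but adjusted p = 0.114 with an estimated correlation). In the TGF-beta response list 12 of 32 fell and 4 rose, or 15 and 5 when adjusted over the list alone. NEDD9, a scaffold protein of focal adhesions, changed by -1.29 ± 0.06, the ligand TGFB2 by -0.81 ± 0.09 and ID3 by -0.51 ± 0.05, whereas ADAM19 (1.06 ± 0.24), BAMBI (0.40 ± 0.09), CCN1 (0.37 ± 0.08) and PDGFB (0.31 ± 0.08) rose (camera adjusted p = 0.00351, but adjusted p = 0.175 with an estimated correlation). With the parental population as a block AURKA, BAMBI and PDGFB lost their calls, with adjusted p = 0.0668, 0.0645 and 0.0995.

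The EGFR ligand and receptor list rose in 30D, with 6 of 20 higher and none lower, also when adjusted over the list alone. Its feedback regulators DUSP6 and SPRY4 rose by 0.79 ± 0.10 and 0.75 ± 0.10, and the ligands HBEGF and TGFA by 0.82 ± 0.12 and 0.44 ± 0.06 (camera adjusted p = 0.0161, but adjusted p = 0.344 with an estimated correlation). Without 30D replicate 2 its adjusted p was 0.0546. Squamous differentiation genes moved in both directions, 8 of 43 rising and 3 falling, or 12 and 3 when adjusted over the list alone. SLPI, a secreted protease inhibitor, and the serine protease TMPRSS11E rose by 1.07 ± 0.06 and 0.91 ± 0.10. The suprabasal keratin KRT13 changed by -1.04 ± 0.06, the cornified envelope protein SPRR3 by -0.93 ± 0.05 and KLK6 by -0.37 ± 0.09. The list's median was 0.19 (camera adjusted p = 0.0258, but adjusted p = 0.373 with an estimated correlation). With no filter on dim probe sets its adjusted p was 0.0548. No other list passed in KYSE30.

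Several genes of motility and adhesion moved singly in 30D. In the integrin and focal adhesion list 6 of 29 rose and 2 fell, or 6 and 3 when adjusted over the list alone, among them PARVA, a link between integrins and actin (0.48 ± 0.07), and the integrin subunit ITGB8 (-0.72 ± 0.06). In the actin motility list 8 of 51 rose and 3 fell, or 11 and 4 when adjusted over the list alone, with TPM1 at 0.56 ± 0.07 and VAV3 at -0.59 ± 0.08. Matrix proteases and inhibitors had 11 of 32 higher and 4 lower, or 12 and 4 when adjusted over the list alone, with ADAM12 at 0.82 ± 0.07 and ADAMTS1, which lay below the filter value in 30D, at least 1.44-fold lower. The higher ones include MMP1, whose levels of 2.57 in 30U and 3.22 in 30D both lay below the filter value, so it is not read as a rise. The camera adjusted p of these 3 lists was 0.0674, 0.106 and 0.166. In the epithelial junction list 8 of 37 rose and 3 fell, or 9 and 4 when adjusted over the list alone (camera adjusted p = 0.18). Its desmosomal cadherin DSC3 changed by -1.28 ± 0.07 and the tight junction gene CLDN7 by 0.46 ± 0.06. MYC rose by 1.02 ± 0.06 and EGR1 fell by 1.01, both in the AP-1 and immediate early list, of which 6 of 18 rose and 5 fell, or 6 and 6 when adjusted over the list alone (camera adjusted p = 0.876). In the basal squamous list 3 of 17 rose and 5 fell, or 5 and 5 when adjusted over the list alone, with LAMB3 at 0.76 ± 0.06 and DST at -0.98 ± 0.07 (camera adjusted p = 0.976, with a median of 0.13 and a mean of -0.04). In the NRF2 target list 5 of 38 rose and 11 fell, or 6 and 13 when adjusted over the list alone, with the cystine transporter SLC7A11 at -0.86 ± 0.08 (camera adjusted p = 0.119).

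In KYSE180, HMCN1, an extracellular matrix protein of the fibulin family, had the largest fitted change in 180D (2.90 ± 0.08, limma adjusted p = 3.24e-05), with mean log2 levels of 4.44 in 180U and 7.34 in 180D. Measured from the filter value of 4.46, it was at least 7.37-fold higher. PRR16 rose 4.28-fold. MMP16, a membrane-type matrix metalloproteinase, PLAT, the tissue plasminogen activator, and GLRB lay below the filter value in 180U and were at least 2.78-fold, 1.42-fold and 2.08-fold higher. EPB41L4A rose by 1.77 ± 0.09, FAT4, an atypical cadherin, by 1.71 ± 0.10, SCG2 by 1.63 ± 0.07 and FLG, the filaggrin gene of the cornified layer, by 1.58 ± 0.10. LIMCH1 rose by 1.42 ± 0.07. LRATD1 had the largest fitted change among the genes lower in 180D (-2.13 ± 0.10, adjusted p = 0.000118), and it was at least 2.58-fold lower, since its 180D level lay below the filter value, so its rank depends on background. KRTDAP, SPRR1A, SPRR1B and FOXN1, all tied to keratinocyte differentiation, changed by -1.94 ± 0.26, -1.83 ± 0.07, -1.37 ± 0.07 and -1.55 ± 0.11. The neuropeptide gene NTS changed by -1.65 ± 0.15, IFI27 by -1.65 ± 0.07, GPNMB by -1.62 ± 0.21, SYTL5 by -1.52 ± 0.07 and the neurotrophin gene BDNF by -1.39 ± 0.08. The call of KRTDAP was not kept with the parental population as a block (adjusted p = 0.0540) or without 180U replicate 1, 180U replicate 2 or 180D replicate 1 (adjusted p up to 0.0839). GPNMB lost its call without the same 3 arrays (adjusted p up to 0.0693), and MMP16 without 180D replicate 1 or 180D replicate 2 (adjusted p up to 0.0675).

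In all, 532 genes differed between 180D and 180U, 361 higher and 171 lower in 180D, and 49 of them changed at least 2-fold, 30 higher and 19 lower. With the parental population as a block 230 genes passed, 213 of them among the 532. Fitting only the KYSE180 arrays gave 195 genes, and an intensity trend in eBayes over all arrays gave 1069. With each array centred on its median over the tested genes the split was 269 higher and 236 lower. The count fell when any 1 array was left out. It fell most without 180D replicate 1, the array with the divergent control probe sets. It fell least without 180D replicate 2, which left that divergent array as the only 180D array. The count in KYSE180 therefore depended on 180D replicate 1 more than on any other array.

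Squamous differentiation genes fell in 180D, with 10 of 43 lower, 3 higher and 30 not passing, or 16 and 6 when adjusted over the list alone. Besides SPRR1A and SPRR1B, SPRR3 changed by -0.76 ± 0.05, while FLG, KRT80 and SCEL (0.39 ± 0.07) rose. KRT80 lay below the filter value in 180U and was at least 1.69-fold higher. The rise of SCEL was not kept with the parental population as a block (adjusted p = 0.0800). The list's median was -0.13 (camera adjusted p = 6.93e-05, but adjusted p = 0.359 with an estimated correlation). Without 180D replicate 1, whose RNA control signals diverged, the adjusted p was 0.000109. Cholesterol synthesis genes rose, with 6 of 22 higher and none lower, or 10 when adjusted over the list alone. INSIG1 rose by 0.60 ± 0.06, HMGCS1 by 0.39 ± 0.05 and IDI1 by 0.35 ± 0.06, with a list median of 0.16 (camera adjusted p = 0.000116, but adjusted p = 0.225 with an estimated correlation). HMGCS1 and IDI1 did not pass with the parental population as a block (adjusted p = 0.0601 and 0.0655). HMGCS1 also lost its call without 180U replicate 1, 180U replicate 2 or 180D replicate 1 (adjusted p up to 0.0625), and IDI1 without any array other than 180D replicate 2 (adjusted p up to 0.0870). Without 180D replicate 1 the list's adjusted p was 0.000143. No other list passed in KYSE180.

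The type I interferon response list in 180D had 8 of 37 members higher, 2 lower and 27 not passing, or 11 and 3 when adjusted over the list alone, and a median of 0.14 (camera adjusted p = 0.0831). IFIT3 rose by 0.91 ± 0.08, IFIT2 by 0.55 ± 0.06 and IRF9, a subunit of the interferon-activated transcription factor ISGF3, by 0.54 ± 0.05. IFI27 fell, as did IFI6 (-0.69 ± 0.10, but adjusted p = 0.0737 with the parental population as a block). Genes of adhesion and matrix moved singly in 180D. In the integrin and focal adhesion list, FERMT2, an activator of integrins, rose by 1.12 ± 0.06 and PARVA by 0.48 ± 0.07, with none lower among 29, or 3 higher when adjusted over the list alone (camera adjusted p = 0.933, with a median just below 0 and a mean of 0.05). PARVA did not pass with the block (adjusted p = 0.0518) or without 180U replicate 1, 180D replicate 1 or 180D replicate 2 (adjusted p up to 0.0685). Among the matrix proteases and inhibitors, 3 of 32 rose and 2 fell, or 6 and 4 when adjusted over the list alone (camera adjusted p = 0.406). Besides PLAT, the gelatinase MMP2 rose by 0.91 ± 0.07, while the collagenase MMP1 fell 2.47-fold (-1.30 ± 0.08). CTSS (0.52 ± 0.08) and ADAM12 (-0.36 ± 0.07), the other members that passed, did not do so with the block (adjusted p = 0.0698 and 0.107), nor did CTSS without any 1 of the 4 KYSE180 arrays (adjusted p up to 0.0931). In the TGF-beta response list 7 of 32 rose and 2 fell, or 12 and 3 when adjusted over the list alone, with NEDD9 at 0.95 ± 0.06, the basement membrane collagens COL4A1 and COL4A2 at 0.71 ± 0.05 and 0.72 ± 0.08, and THBS1 at 0.57 ± 0.06 (camera adjusted p = 0.196). The members that fell, TSC22D1 (-0.23 ± 0.05) and TNC (-0.38 ± 0.07), did not pass with the block (adjusted p = 0.132 and 0.107).

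The change from U to D differed between the lines for 1723 genes by a direct test of the difference, with 984 higher and 739 lower in KYSE180 relative to KYSE30. GJA1, at a mean log2 level of 12.27 in 180U and 12.34 in 180D, had the largest fitted difference (4.79 ± 0.08, limma adjusted p = 8.57e-07), though its rank depends on background, since its 30D level lay below the filter value. EPB41L4A fell in 30D and rose in 180D, a difference of 3.98 ± 0.13. The collagen gene COL12A1 (-1.66 ± 0.08 in KYSE30, 0.85 ± 0.08 in KYSE180), NEDD9, LIMCH1 and GDF15 also moved in opposite directions, with differences of 2.51, 2.24, 2.60 and 2.23. HMCN1, KLHL13, IGFBP5 and SPP1 had differences of 3.08, 2.92, 2.83 and 2.23. In the other direction, IFI27 rose in 30D and fell in 180D, a difference of -3.50 ± 0.09, and IFI6, RFTN1 and GBP1 had differences of -2.65, -2.51 and -2.24. SPRR1A and SPRR1B had differences of -2.41 and -1.83, IL1RN of -1.78 and NTS of -1.81. NT5E, a cell surface nucleotidase, had one of -1.71 ± 0.19. MMP1 had a difference of -1.95 ± 0.12, and it fell in 180D from a level of 10.00, while both of its KYSE30 levels lay below the filter value. Of the genes in this paragraph GJA1, KLHL13, IGFBP5, SPP1, IFI27, HMCN1, GDF15 and NTS also had at least 1 group mean below it, so the sizes and the order of their differences depend on background.

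At least a 2-fold difference between the lines was reached by 191 genes, 127 higher and 64 lower. With the parental population as a block 1011 genes passed, 954 of them among the 1723. The count was 764 without 30U replicate 1, 739 without 30U replicate 2, 727 without 30D replicate 1, 781 without 30D replicate 2 and 1104 without 180U replicate 2. Without 180D replicate 1 it was 1306.

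By the preset correlation 9 lists differed between the lines, and for the interferon and cholesterol lists the call held with an estimated correlation. In the interferon list 27 of 37 members had a lower change in KYSE180 and 2, IFIT2 and IFIT3, a higher one, or 29 and 5 when adjusted over the list alone (camera adjusted p = 8.10e-14, and adjusted p = 0.0221 with an estimated correlation). In the cholesterol list 14 of 22 had a higher change in KYSE180 and none a lower one, or 17 when adjusted over the list alone (camera adjusted p = 6.01e-09, and adjusted p = 0.0329 with an estimated correlation). MHC genes had 10 of 16 lower, or 11 when adjusted over the list alone (adjusted p = 2.86e-06, but adjusted p = 0.153 with an estimated correlation). The cell cycle list had 10 of 50 higher, or 14 when adjusted over the list alone (adjusted p = 1.33e-05, but adjusted p = 0.232 with an estimated correlation). In the squamous differentiation list 15 of 43 were lower and 3 higher, counts that were the same when adjusted over the list alone (adjusted p = 0.000143, but adjusted p = 0.156 with an estimated correlation). The higher ones were KRT13, FLG and KRT80. The TGF-beta list had 16 of 32 higher and 4 lower by both adjustments (adjusted p = 0.000315, but adjusted p = 0.146 with an estimated correlation). The p53 list had 7 of 20 higher and TP53I3 lower, or 9 and 1 when adjusted over the list alone (adjusted p = 0.00277, but adjusted p = 0.146 with an estimated correlation). The call of TP53I3 ended with the parental population as a block (adjusted p = 0.0699).

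The hypoxia and glycolysis list had 5 of 32 lower and 2 higher, or 7 and 2 when adjusted over the list alone, among them NDRG1 (-1.07 ± 0.07) and the hexokinase HK2 (-0.73 ± 0.10). Its camera adjusted p was 0.0287, 0.156 with an estimated correlation, 0.0809 without 180U replicate 1 and 0.0621 without 180D replicate 2. Within the lines this list had an adjusted p of 0.147 in KYSE30 and 0.194 in KYSE180. The EGFR list had 5 of 20 lower and none higher, or 7 and 3 when adjusted over the list alone, with TGFA at -0.77 ± 0.09 and HBEGF at -1.05 ± 0.17. Its camera adjusted p was 0.0338 and 0.323 with an estimated correlation. It was 0.0529 without 30D replicate 2, 0.0791 without 180U replicate 1 and 0.103 without 180D replicate 2.

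**Figure D2:**
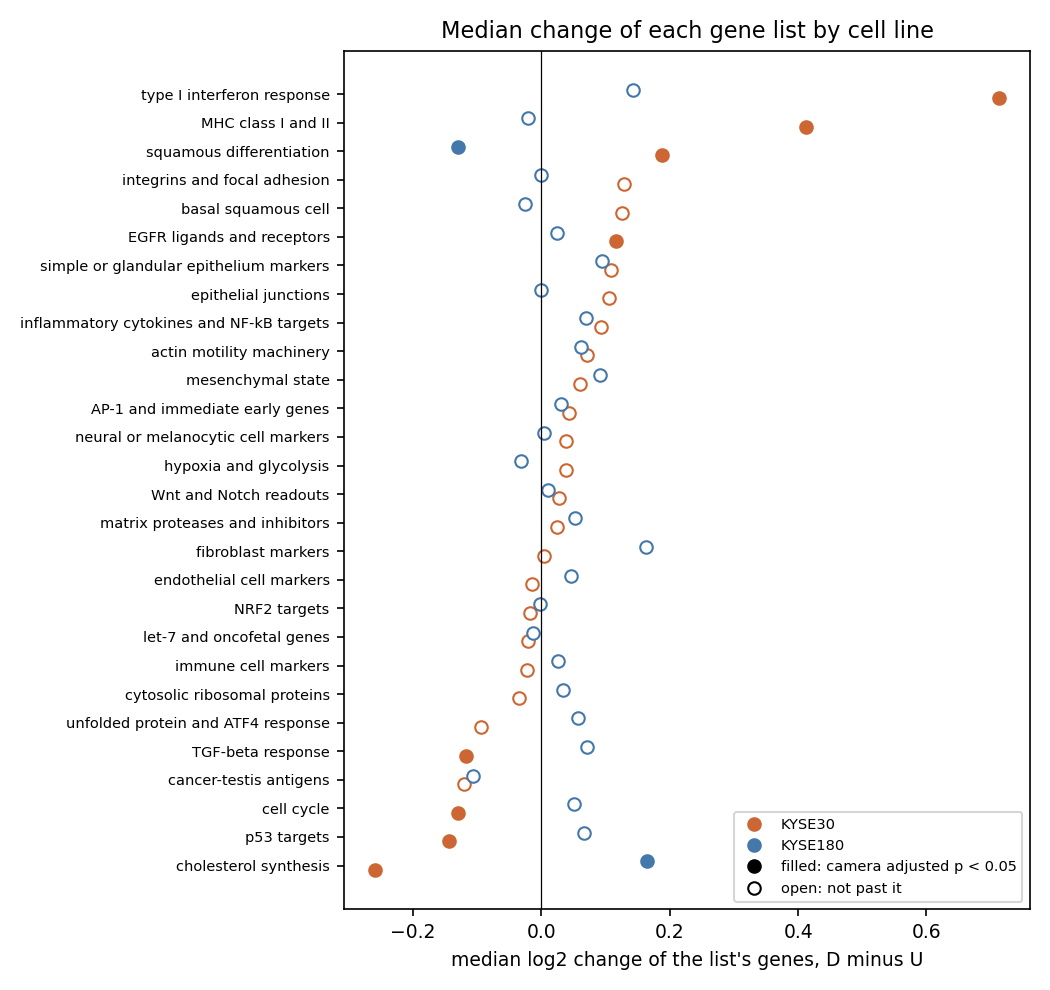
Median log2 change, D minus U, of the measured genes of each of the 28 lists in KYSE30 and KYSE180, with filled points where the camera adjusted p was under 0.05. The interferon list lies at 0.71 and 0.14, and the cholesterol list at -0.26 and 0.16.

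The comparison over both lines asked for changes that they share. With both lines in 1 additive fit, 124 genes differed between D and U, 79 higher and 45 lower in D, 5 of them by at least 2-fold. With the parental population as a block limma called 0 genes, with a smallest adjusted p of 0.0953 and 1659 genes at an unadjusted p under 0.05. An intensity trend gave 195 genes. The mean of the within-line contrasts, whose spread leaves out the difference between the lines, gave 1281. SPRR3 (-0.84 ± 0.05, limma adjusted p = 0.00190) fell in both lines. FOXC2, a transcription factor linked to mesenchymal states, rose by 0.77 ± 0.06, the sodium leak channel gene NALCN by 0.74 ± 0.06, CXCL8, the interleukin-8 gene, by 0.80 ± 0.08, IRF9 by 0.73 ± 0.08 and S100P by 0.70 ± 0.07. These 6 genes kept their call in all 8 fits without 1 array. The other 14 genes with the largest changes lost it in 1 or more of them. Among these, LRATD1 (-1.54 ± 0.22), PLA2G4A (-1.40 ± 0.16), SMOC2 (-1.23 ± 0.16), BDNF (-1.01 ± 0.14), PRXL2A, HEY1, SESN3, ARMCX6 and DAPK1 were lower in D, and PTPRB (1.00 ± 0.14), THSD4, LGALS1, KMO and MT1H were higher. LRATD1, PLA2G4A, SMOC2, SESN3, PTPRB and KMO had a group mean below the filter value, so the sizes and the order of their changes depend on background. For KMO in KYSE30 (3.60 and 4.37) and PTPRB in KYSE180 (2.97 and 4.27) both means lay below it, so these are not read as rises there. MT1H has near-identical paralogs, so its signal cannot be assigned to it with certainty. The count over all genes was 26 without 30U replicate 1, 35 without 30U replicate 2, 30 without 30D replicate 1 and 16 without 30D replicate 2. It was 47 without 180U replicate 1, 72 without 180U replicate 2, 52 without 180D replicate 1 and 77 without 180D replicate 2. With each array centred on its median the split was 63 higher and 63 lower.

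The interferon list was higher in D over both lines, with IRF9 and IFIT1 (0.33 ± 0.05) passing of 37, or 22 higher and none lower when adjusted over the list alone (camera adjusted p = 1.17e-12, but adjusted p = 0.405 with an estimated correlation). No MHC gene passed of 16, or 2 higher when adjusted over the list alone (adjusted p = 0.00390, but adjusted p = 0.530 with an estimated correlation). These averages came mainly from KYSE30 and are not read as changes shared by the lines. The interferon median was 0.71 in KYSE30 and 0.14 in KYSE180, where camera gave an adjusted p of 0.0831. The MHC median was 0.41 in KYSE30 and -0.02 in KYSE180. Without 30U replicate 1 the adjusted p of the MHC list was 0.0544. In the actin motility list GSN, the actin-severing protein gelsolin (0.40 ± 0.05), and CDC42EP1 (0.39 ± 0.05) passed of 51, also when adjusted over the list alone (adjusted p = 0.0352, but adjusted p = 0.530 with an estimated correlation). The adjusted p of that list was 0.0638 without 30U replicate 1, 0.0681 without 180U replicate 2 and 0.0798 without 180D replicate 1, and 0.104 with the mean of all probe sets of a gene. IFIT1 lost its call without any of the 8 arrays, GSN without 30U replicate 1, 30U replicate 2 or 30D replicate 2, and CDC42EP1 without any array other than 180D replicate 2, with adjusted p of up to 0.109, 0.0640 and 0.0942.

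**Figure D3:**
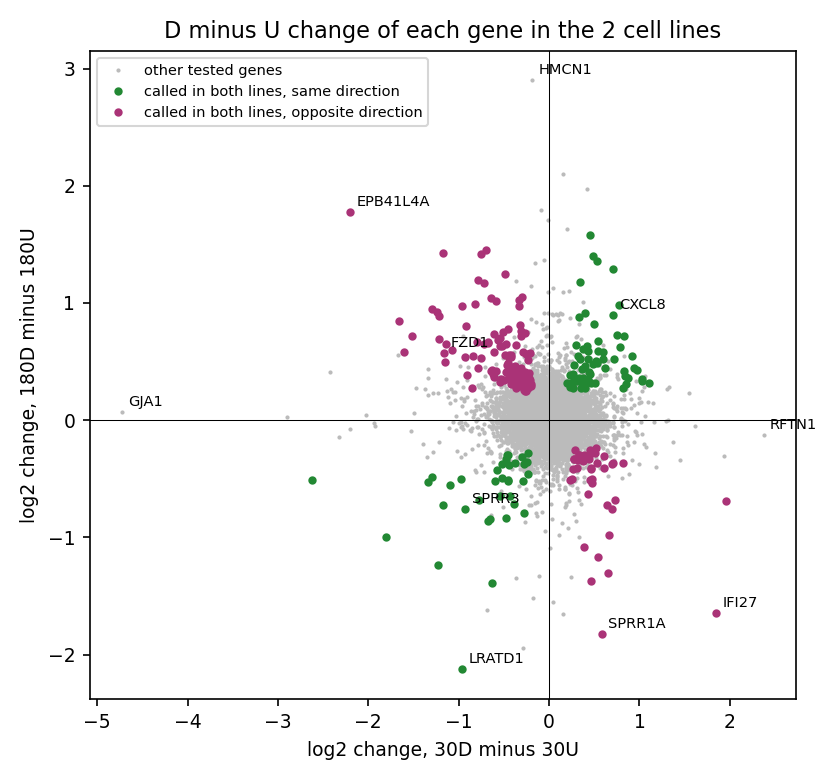
Log2 change of each of the 14180 tested genes, 30D minus 30U on the horizontal axis and 180D minus 180U on the vertical axis. Of 253 genes called in both lines (coloured), 102 moved in the same direction and 151 in opposite directions.

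Across the tested genes, which are not independent replicates, the changes in both lines correlated at -0.07 (Pearson). The genes called in both lines numbered 253, of which 66 rose and 36 fell in both, 111 fell in 30D and rose in 180D, and 40 rose in 30D and fell in 180D. Independent lists of these sizes would share 30.4, 13.9, 29.3 and 14.4 genes. Because the lines share no array but share each gene's estimated spread, the fold changes were also shuffled among genes with each spread kept, which was chosen after the data were seen. In 200 shuffles the means were 60.2, 37.3, 58.2 and 37.4 and the highest counts 84, 55, 80 and 51. Only the 111 genes lower in 30D and higher in 180D lay outside this range, though the number called in KYSE180 could vary between shuffles. Fits made separately for each line share no estimate of spread, and they gave 23, 20, 50 and 15 genes in the same order. Independent lists of those sizes would share 13.5, 6.63, 12.4 and 7.23, so each of these counts was above that number. All 151 genes with opposite calls also passed the test of the difference. It comes from the same fit with the same spread, so opposite calls all but force it to pass, and this adds no support. Of 2093 genes called only in KYSE30, 1116 passed that test, as did 184 of 279 called only in KYSE180.

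The lines themselves differed far more than D and U did. Of the genes tested 9518 differed between KYSE180 and KYSE30, 5119 higher and 4399 lower in KYSE180, and 2434 by at least 2-fold (1185 higher, 1249 lower). KRT14, CSTA and AKR1C3 lay below the filter value in KYSE30 and PEG10 in KYSE180, and differences against so low a level depend on background. The basal keratin gene KRT14 was higher in KYSE180 by 9.66 ± 0.16 (limma adjusted p = 8.63e-10), CSTA, a cystatin of the cornified envelope, by 9.39 ± 0.08, and the aldo-keto reductase gene AKR1C3 by 9.50 ± 0.06. AKR1B10 and AKR1C1 were higher by 8.19 ± 0.09 and 8.08 ± 0.11, and signals of the near-identical AKR1C genes cannot be assigned to single members with certainty. TENM2, CALB1, MFAP5, PDCD6P1 and MSN, the actin-membrane linker moesin, were higher by 8.82, 8.78, 8.12, 8.19 and 8.50. In KYSE30 the imprinted gene PEG10 was higher, at -7.83 ± 0.08 as KYSE180 minus KYSE30. PKIB, the cancer-testis gene MAGEB2, VGLL1, SPOCK1 and PADI3 differed by -7.64, -7.42, -7.33, -6.67 and -6.67. ITGBL1, CST6, the prostaglandin receptor PTGER4 and the cyclin-dependent kinase inhibitor CDKN2B differed by -6.52, -6.50, -6.45 and -6.38.

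NRF2 targets, genes of the oxidative stress response, were higher in KYSE180, with 33 of 38 higher and none lower by both adjustments. AKR1C3, AKR1B10 and ALDH3A1 (5.68 ± 0.07) were examples, and the median was 1.35 (camera adjusted p = 1.97e-10, but adjusted p = 0.0513 with an estimated correlation). Basal squamous genes were higher, with 13 of 17 higher and 4 lower by both adjustments, among them KRT5 (7.55 ± 0.08) and PDPN (5.84 ± 0.05) (adjusted p = 0.0182, but adjusted p = 0.279 with an estimated correlation). The lower ones were ITGB4, BNC1, TFAP2A and TFAP2C. Squamous differentiation genes had 27 of 43 higher and 10 lower by both adjustments (adjusted p = 0.0345, but adjusted p = 0.642 with an estimated correlation, and adjusted p = 0.0518 without 180U replicate 1). Wnt and Notch readouts had 18 of 27 higher and 4 lower by both adjustments, with WNT5A at 7.85 ± 0.10 and DKK1 at -2.13 ± 0.05 (adjusted p = 0.0270, but adjusted p = 0.530 with an estimated correlation).

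Other lists were lower in KYSE180. The EGFR list had 16 of 20 lower and 3 higher, with the ligand EREG at -5.95 ± 0.06 (adjusted p = 0.000230, but adjusted p = 0.233 with an estimated correlation). The TGF-beta list had 24 of 32 lower and 3 higher, with TGFBI at -6.01 ± 0.06 (adjusted p = 0.000116, but adjusted p = 0.370 with an estimated correlation). The integrin and focal adhesion list had 20 of 29 lower and 4 higher, with ITGAV at -1.61 ± 0.05 and ITGA2 at -1.64 ± 0.05 (adjusted p = 0.00204, but adjusted p = 0.424 with an estimated correlation). The cholesterol list had 18 of 22 lower and 3 higher, with DHCR7 at -2.91 ± 0.09 (adjusted p = 0.00204, but adjusted p = 0.667 with an estimated correlation). The AP-1 list had 12 of 18 lower and 3 higher, with KLF6 at -2.24 ± 0.05 (adjusted p = 0.00289, but adjusted p = 0.233 with an estimated correlation). The actin motility list had 28 of 51 lower and 12 higher, with RND3 at -2.15 ± 0.05 (adjusted p = 0.0124, but adjusted p = 0.519 with an estimated correlation). The counts of these 6 lists were the same when adjusted over the list alone.

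Genes often used to describe epithelial and mesenchymal states were compared in every contrast. CDH1, the E-cadherin gene, stood at 0.17 ± 0.06 in KYSE30 and -0.02 ± 0.06 in KYSE180 and did not pass in either (adjusted p = 0.0941 and 0.868). CDH2, the N-cadherin gene, rose 1.82-fold in 180D (0.87 ± 0.12, adjusted p = 0.00984), with 0.23 ± 0.12 in KYSE30. Its call ended without 180U replicate 1 or 180U replicate 2 (adjusted p = 0.0575 and 0.0731), and the test of the difference gave an adjusted p of 0.0474 that was 0.0526 with the parental population as a block and up to 0.143 without any array other than 180D replicate 1. VIM stood at 0.29 ± 0.11 and -0.24 ± 0.11 (adjusted p = 0.141 and 0.322) and FN1 at -0.31 ± 0.34 and -0.21 ± 0.34 (adjusted p = 0.598 and 0.785), and both were lower in KYSE180 than in KYSE30 (-3.16 ± 0.12 and -3.55 ± 0.23). SNAI2 rose by 0.31 ± 0.05 in 30D (adjusted p = 0.0109) and stood at -0.20 ± 0.05 in KYSE180. The call of SNAI2 ended without any of the 4 KYSE30 arrays (adjusted p between 0.0562 and 0.0824). KRT14 passed in 30D (0.59 ± 0.10), though not without 30U replicate 2 (adjusted p = 0.0615), but its KYSE30 levels of 3.54 and 4.13 both lay below the filter value, so it is not read as a rise. KRT5 and ITGA6 did not pass within either line. ITGA6 was higher in KYSE180 (0.31 ± 0.12, adjusted p = 0.0435), but not without 30U replicate 1, 30U replicate 2, 180U replicate 1, 180U replicate 2 or 180D replicate 1 (adjusted p up to 0.120), with the mean of all its probe sets (adjusted p = 0.0572) or with quantile normalization once more (adjusted p = 0.0604).

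In the mesenchymal list 4 of 32 genes rose and 2 fell in 30D, or 5 and 3 when adjusted over the list alone (camera adjusted p = 0.306), and 6 rose and 2 fell in 180D, or 9 and 4 when adjusted over the list alone (adjusted p = 0.237). FOXC2 rose in both lines (0.83 ± 0.08 and 0.72 ± 0.08). CD44 rose in 30D (0.47 ± 0.07), COL5A2 rose in 180D (0.85 ± 0.07) and NT5E fell in 180D (-1.17 ± 0.13). The epithelial junction list in 180D had PKP2 higher (0.56 ± 0.07) and DSC2 lower of 37, the same by adjustment over the list alone (adjusted p = 0.68). The call of PKP2 ended without 180U replicate 1 (adjusted p = 0.0523). That of DSC2 (-0.38 ± 0.06) was not kept with the block (adjusted p = 0.0551) or without any 1 of the 4 KYSE180 arrays (adjusted p up to 0.0934). The inflammatory and NF-kB list had 5 of 21 higher and 3 lower in 30D by both adjustments (camera adjusted p = 0.18), and CXCL8 (0.90 ± 0.11) and C3 (0.64 ± 0.05) higher in 180D, or 6 higher and 1 lower when adjusted over the list alone (adjusted p = 0.263). Without 180U replicate 2 the adjusted p of CXCL8 was 0.0541. The unfolded protein and ATF4 list had 4 of 29 higher and 7 lower in 30D, or 5 and 10 when adjusted over the list alone (adjusted p = 0.119), and 3 higher in 180D by both adjustments (adjusted p = 0.237), with ATF3 at -0.84 ± 0.07 and 0.55 ± 0.07. Cytosolic ribosomal proteins had none of 25 past the threshold in either line by both adjustments (adjusted p = 0.18 and 0.406). Cancer-testis antigens had none of 13, with MAGEA1 lower in 180D when adjusted over the list alone (adjusted p = 0.266 and 0.194). The let-7 and oncofetal list had ARID3B (0.42 ± 0.08) and E2F5 (0.54 ± 0.11) higher of 16 in 30D and none in 180D, or 2 higher and 1 lower in 30D and 1 higher in 180D when adjusted over the list alone (adjusted p = 0.981 and 0.887). The calls of ARID3B and E2F5 ended without 30U replicate 2, 30D replicate 1 or 30D replicate 2 (adjusted p up to 0.0956 and 0.0949).

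Median levels of the markers of other cell types lay near the filter value or below it, apart from simple or glandular epithelium. The filter was passed by 4 of 10 fibroblast, 6 of 14 immune and 5 of 9 endothelial markers. It was also passed by 6 of 10 neural or melanocytic and 11 of 14 glandular markers. The median marker level in KYSE30 was 3.70 for fibroblasts, 4.33 for immune cells, 4.87 for endothelial cells and 4.76 for neural or melanocytic cells, against a filter value of 4.46, and 5.61 for simple or glandular epithelium. With all genes tested and no filter, the endothelial gene CDH5 was lower in 30D (-0.40, adjusted p = 0.0395), GATA6 was higher in 30D (0.28, adjusted p = 0.0484) and in 180D (0.47, adjusted p = 0.0224), and KRT7 was higher in 180D (0.40, adjusted p = 0.0436). As lists, the camera adjusted p in KYSE30 and KYSE180 was 0.759 and 0.237 for fibroblasts, 0.814 and 0.68 for immune cells, 0.814 and 0.701 for endothelial cells, 0.802 and 0.882 for neural or melanocytic cells, and 0.207 and 0.237 for simple or glandular epithelium. COL1A1, the fibroblast marker that passed with the filter in 180D (0.58 ± 0.11), did not pass with the parental population as a block (adjusted p = 0.108) or without any array other than 180D replicate 2 (adjusted p up to 0.153). With the filter, GATA6 lost its call in 30D without any of the 4 KYSE30 arrays (adjusted p up to 0.15) and in 180D without 180U replicate 1, 180U replicate 2 or 180D replicate 1 (adjusted p up to 0.0639). KRT7 lost its call in 180D with the block (adjusted p = 0.0637) and without 180U replicate 1, 180D replicate 1 or 180D replicate 2 (adjusted p up to 0.0986).

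Some calls of single genes rested on the probe set with the highest mean. With the mean of all probe sets of a gene, ADAMTS1 did not pass in 30D (adjusted p = 0.126). In 180D, ATF3, PARVA, PKP2, COL1A1, KRT7, NT5E, IDI1 and HMGCS1 did not pass, with adjusted p of 0.0693, 0.0735, 0.0884, 0.0967, 0.103, 0.105, 0.117 and 0.155. GATA6 did not pass in either line (adjusted p = 0.653 and 0.515). The difference between the lines did not pass for HBEGF and HK2 (adjusted p = 0.0514 and 0.116), nor the change over both lines for LGALS1, SESN3 and GSN (adjusted p = 0.0509, 0.0875 and 0.254). With quantile normalization once more, SESN3 over both lines and the difference of CDH2 had adjusted p of 0.0514 and 0.0505.

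In several lists that did not pass, the median, the mean and the camera direction differed in sign. In KYSE30 these were the Wnt and Notch, basal squamous, let-7, fibroblast and immune lists, and in KYSE180 the MHC, epithelial junction, EGFR, let-7, integrin, endothelial and neural or melanocytic lists. In the test of the difference they were the actin motility, matrix protease, let-7, cancer-testis, glandular, AP-1 and inflammatory lists, and over both lines the ribosomal protein, let-7 and basal squamous lists. Between the lines they were the mesenchymal, interferon, matrix protease, inflammatory, MHC, immune and neural or melanocytic lists.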

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

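The tests of a single array were chosen only after the results below had been seen.

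The change from U to D differed between KYSE30 and KYSE180 for 1723 genes by the direct test of the difference, limma with Benjamini-Hochberg adjustment. Of the genes that passed it, 110 named above for changes from U to D are listed here, 62 with a higher and 48 with a lower change in KYSE180. The list leaves out genes named only for the comparison of the lines, for the effect of a setting or among the other observations. Where a gene lay below the filter value in a group, as GJA1 did in 30D, the size of its difference depends on background. The log2 differences on the higher side were GJA1 4.79, EPB41L4A 3.98, HMCN1 3.08, KLHL13 2.92, IGFBP5 2.83, LIMCH1 2.60, COL12A1 2.51, NEDD9 2.24, GDF15 2.23, SPP1 2.23, FREM2 2.18, GLRB 2.14, CNTN1 2.13, C1orf21 2.11, PALMD 2.07 and PRR16 1.94. Smaller ones were SOX2 1.91, PLAT 1.88, BCAT1 1.87, FAT4 1.72, INSIG1 1.67, MMP16 1.55, SCG2 1.43, ATF3 1.39, EGR1 1.34, KRT13 1.20, FLG 1.13, TP53INP1 1.09, FERMT2 1.08, IFIT2 1.04, DSC3 1.02 and HMGCS1 1.01. Below these lay PKP2 0.98, COL1A1 0.97, IFIT3 0.97, DST 0.97, TGFB2 0.93, MMP2 0.92, LGALS1 0.91, ADAMTS1 0.88, IDI1 0.88, KRT80 0.88, STARD4 0.87, CDKN1A 0.87, THSD4 0.83, VAV3 0.82, HEY1 0.81 and SESN3 0.80. The remaining genes on this side were PLA2G4A 0.80, SESN1 0.78, SLC7A11 0.77, COL5A2 0.75, ID3 0.71, COL4A1 0.70, THBS1 0.70, COL4A2 0.69, ITGB8 0.69, C3 0.67, MCM7 0.64, CDH2 0.64, ARMCX6 0.55 and TYMS 0.51. On the lower side they were IFI27 -3.50, IFI6 -2.65, RFTN1 -2.51, SPRR1A -2.41, GBP1 -2.24, MMP1 -1.95, SPRR1B -1.83, NTS -1.81, IL1RN -1.78, NT5E -1.71, COXFA4L3 -1.67, KRTDAP -1.65, FOXN1 -1.60, IFI44 -1.56, SYTL5 -1.34 and LAMP3 -1.32. Next came PRR15L -1.31, SLPI -1.30, ADAM12 -1.19, LRATD1 -1.17, NDRG1 -1.07, HBEGF -1.05, CCL5 -1.04, MYC -1.03, ISG15 -1.0, SPRY4 -0.88, LAMB3 -0.86, KRT14 -0.83, TAP1 -0.82, TMPRSS11E -0.80, TGFA -0.77 and BDNF -0.75. The remaining genes on this side were HK2 -0.73, DUSP6 -0.69, PDGFB -0.65, BAMBI -0.59, TPM1 -0.57, MT1H -0.55, HLA-F -0.55, CCN1 -0.53, SNAI2 -0.50, PSMB9 -0.50, DSC2 -0.48, CD44 -0.44, TP53I3 -0.42, CLDN7 -0.42, IRF9 -0.37 and TSC22D1 -0.31. With the parental population as a block the adjusted p of the difference was 0.05 or more for TPM1 (0.0501), PDGFB (0.0507), CDH2 (0.0526), PSMB9 (0.0555), IRF9 (0.0568), DUSP6 (0.0684), TP53I3 (0.0699), BAMBI (0.0727), KRTDAP (0.0779), TSC22D1 (0.0783) and MMP16 (0.0855). The call of CDH2 also ended without any array other than 180D replicate 1 (adjusted p up to 0.143), and that of DSC2 without 30U replicate 1 or 30D replicate 2 (adjusted p = 0.0585 and 0.0594).

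By camera 9 lists differed between the lines. The adjusted p was 8.10e-14 for the interferon list, 6.01e-09 for cholesterol synthesis, 2.86e-06 for MHC genes, 1.33e-05 for the cell cycle, 0.000143 for squamous differentiation, 0.000315 for the TGF-beta response, 0.00277 for p53 targets, 0.0287 for hypoxia and glycolysis and 0.0338 for EGFR ligands and receptors. With an estimated correlation the interferon and cholesterol lists passed, and the adjusted p of the other 7 lay between 0.146 and 0.323.

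Control probe sets, which the comparisons do not use, differed on 180D replicate 1. The 3′ minus 5′ log2 difference of the ACTB controls was 1.92 there and 1.06 to 1.42 on the other 7 arrays, and the 18S control read 11.47 against 12.35 to 12.54.

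The interferon list rose in 30D with a median of 0.71. It did not rest on 1 array, since the highest camera adjusted p without any 1 of the 8 arrays was 1.05e-17. Nor did it rest on blocks of neighbouring genes, since with 1 listed gene kept per neighbourhood, 25 of 37, the camera p was 4.08e-21. The difference of the list between the lines (adjusted p = 0.0221 with an estimated correlation) is what drew attention to it and tests no cause, and a smaller rise in KYSE180 stays open. Raised interferon transcripts in 30D may still account for it, because 0 of the 18 interferon genes on the array were higher by limma but only 2 lay above the filter value, so the test decides nothing, and a biological effect of the selection stays open as untested.

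The cholesterol list fell in 30D and rose in 180D, with medians of -0.26 and 0.16. A single array does not account for the difference, whose highest camera adjusted p without any 1 array was 9.73e-08. Whether a difference in culture density is involved was tested only weakly. A list of YAP and TEAD targets, which follow cell density, differed between the lines with a camera p that was 0.0486, not adjusted for the 3 comparisons. With an estimated correlation that p was 0.296. Of the 22 measured targets 6 are also on the other lists. In 180D the p of that list was 0.0196, and 0.228 with an estimated correlation, whereas in 30D, where cholesterol genes fell, 3 of its 22 genes were higher and 3 lower, with a median of 0.02 and a p that was 0.857. Density and an effect of the selection both stay open.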

How the results depend on the processing

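All alternatives were planned, and no test in this part was chosen after its result was seen. Except where the construction shows it, the cause of a change was not tested. Filtering at the 60th percentile, the mean of all probe sets, quantile normalization once more, centring and robust eBayes left every count of genes within 1.5 times its value. With no filter, which tests more genes, 311 genes passed for 180D against 180U and 1142 for the difference between the lines. With every probe set on its own, which tests more features, 17306 passed between the lines. An intensity trend gave 1069 for 180D against 180U, 2700 for the difference and 195 over both lines. Fitting only the arrays of 1 line gave 195 for 180D against 180U but 2890 for 30D against 30U. Fewer arrays alone therefore do not account for the lower count in KYSE180. Arrays of the same group differed more in KYSE180 (SD across genes of 0.158 and 0.165) than in KYSE30 (0.127 and 0.129). The joint fit shares 1 spread over both lines, so its calls in KYSE180 also lean on the KYSE30 arrays. The mean of the within-line contrasts in the fit of 4 groups, whose spread leaves out the difference between the lines, gave 1281 over both lines. At least a 2-fold change was reached by 85, 49, 191, 5 and 2434 genes in the order 30D against 30U, 180D against 180U, difference, both lines and between the lines.

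With the parental population as a block, 230 genes passed for 180D against 180U, 1011 for the difference and 0 over both lines (limma, 1659 at an unadjusted p under 0.05). The title number as a block, which crosses the pairs of KYSE180, gave 175, 961 and 0. The parental population as a random block gave 45 over both lines, with a consensus correlation of -0.37, against 0.0135 in the fit of 4 groups. The additive residual holds the difference between the changes of the lines, so -0.37 does not show that paired arrays vary in opposite ways. Of the genes that the fixed rule names in a comparison, the parental population as a block ended the calls of 1 for 30D against 30U, 21 for 180D against 180U, 8 for the difference and 30 over both lines, and added 2, 0, 1 and 0. Genes named outside that rule are not in these counts. The count of 30D against 30U stayed within 1.5 times its value, and the lists called by camera in these 4 comparisons passed with the block too. Between the lines no block was fitted.

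Without 1 array the counts ranged from 834 to 2553 for 30D against 30U, from 209 to 502 for 180D against 180U, from 727 to 1702 for the difference, from 16 to 77 over both lines and from 9023 to 9289 between the lines. The correlation across genes ranged from -0.08 to -0.05 without 1 array. With the mean of all probe sets, WNT5A reversed to -0.046 from 0.43 and HMGA2 to -0.22 from 0.19 in KYSE30, and SEL1L to -0.10 from 0.27 in KYSE180. The fry test gave an adjusted p of 0.0528 for the interferon list, 0.173 for MHC genes and 0.0528 for actin motility over both lines. Signals near the low end of the array limit what can be seen of dim genes.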

Other observations

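The test against shuffled gene orders was chosen only after the run below had been seen, and metallothioneins were looked at after their values were seen.

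Metallothioneins, small cysteine-rich proteins that bind zinc and copper, rose together in 30D. MT1F changed by 1.11, MT1X by 1.03, MT1E by 1.01, MT1H by 0.98, MT1G by 0.88, MT1HL1 by 0.84 and MT2A by 0.83 (log2, limma adjusted p of 0.00165 or less). In 180D the same order of genes gave 0.31, 0.35, 0.16, 0.43, 0.36, 0.38 and 0.42, and MT1E did not pass (adjusted p = 0.476). The difference between the lines passed for all 7. All 7 still passed in 30D with the parental population as a block, but in 180D the adjusted p was 0.0540 for MT1HL1, 0.0707 for MT1G, 0.0721 for MT1X and 0.117 for MT1F, and that of the difference was 0.0527 for MT1E. For these comparisons the genes were not refitted without single arrays. These genes are near-identical copies, so single members cannot be told from each other with certainty.

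A run of neighbouring genes was lower in 30D, and its change differed between the lines. The window of 51 genes from TMEM60 to SDHAF3 had a median difference between the lines of 0.25, and 0 of 1000 shuffles of gene order reached it, the highest giving 0.21, so a chance order of genes is argued against. The run was taken as the genes of the windows on this chromosome whose median in 30D minus 30U lay below that of every shuffle. Of its 61 genes 20 were lower and 5 higher in 30D, and 4 were higher and 3 lower in 180D. Lower in 30D were FZD1, a Wnt receptor (-1.16), DLX6-AS1 (-0.69), TMEM243 (-0.55) and TP53TG1 (-0.53), whereas SAMD9L was higher (0.63). A copy-number difference between the sublines might account for the run. Of its 34 well-expressed genes 79.4% were lower in 30D in both parental pairs, against 40.9% of other well-expressed genes. This share lay just under the 80% set for that explanation and above the 60% set against it. Because the run was picked for low values in 30D on the same arrays, a high share was built in, so that test decides nothing. In 180D 50% of the well-expressed run genes were higher in both pairs, against 38.1% of others. The highest window of KYSE180 was another, ZNF394 to MUC17, so a rise of this run in 180D is not claimed. The median of that window was 0.141, and 0 of 1000 shuffles reached it, the highest giving 0.128. In KYSE180 12 windows lay above every shuffle, so neighbouring genes moved together in 180D too. An effect of the selection on the region was not tested.

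Other splits of the 8 arrays into 4 and 4 were fitted in the same way. For D against U over both lines, 2 of 34 splits, the real one included, called as many genes as the real 124, the highest other being 321, so by this count chance could not be excluded. That other split sets 30U and 180D against 30D and 180U, a structure of the samples in which the lines change in opposite directions, which is the contrast of the difference between the lines. Apart from it, no other split called more than 1 gene. Those splits mix U and D arrays within at least 1 line, so the changes from U to D fall into their residual spread. Few calls can arise there, and their low counts are not taken as support for the 124 genes. Among the 8 splits that part as many pairs, 2 called as many, and with the parental population as a block 0 genes passed by limma, with 1659 at an unadjusted p under 0.05. For KYSE180 against KYSE30, 1 of 34 splits, the real one itself, called as many as the real 9518, the highest other being 0. Every other split mixes the lines, so their large difference falls into its residual spread and few calls can arise. The low counts of the other splits follow from that, and no conclusion about chance is drawn from them.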
